A study of Mus musculus with 6 samples.

How the data were processed

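Open chromatin was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA. The samples were cultured mouse dermal fibroblasts, with 3 wildtype (WT) libraries and 3 libraries from cells lacking Lap2alpha (KO), sequenced on an Illumina NextSeq instrument per the labels. The titles number the libraries within each genotype, and no label says whether they came from separate animals or cultures. Per the submitters' processing notes, the authors used Bowtie2 2.5.1, Genrich, deepTools 3.5.1 and the mouse build GRCm38. The version and settings of Genrich, any shift of reads for the Tn5 insertion site, and the way in which the 3 libraries of a genotype were combined were not given in the sources used here.

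The values analysed were 2 peak lists, 1 per genotype, each covering 3 libraries together. The authors deposited for every peak a score with a ceiling of 1000, a signal, the −log10 of the summit p and of its q, and the summit position. The q was not used here. Tested on the deposited values, the score equalled 1000 times the signal divided by the peak length, rounded and held at the ceiling, for 100% of peaks in both lists. It stood at the ceiling for 94.8% of WT and 95.0% of KO peaks, so the signal was used in its place. The deposited signal is an area that grows with peak length, none was below 200 in either list, and it carries no scaling between the lists. It was therefore used only to rank or filter peaks within their own list, as a percentile or a decile of that list.

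With 1 combined list per genotype there is no replicate spread, no p-value was computed between genotypes, and no library could be left out. Peak lists carry no read totals, so the depth of each library is unknown, and a deeper set of libraries gives more weak peaks. A peak called in 1 list only cannot be told from a peak just under the threshold of the other list. Intervals are 95% percentile intervals from 1000 resamplings of 10 Mb blocks of the genome with a fixed seed. They cover variation along the genome only, not variation between libraries or animals.

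A peak was shared if it overlapped a peak of the other list by at least 1 bp, and otherwise was WT-only or KO-only. Gene positions were those of 21887 protein-coding genes of the RefSeq annotation of GRCm38.p6, the build of the peak lists. The gene table used here held gene spans without strand, exons or sequence. The promoter planned around transcription start sites was therefore replaced by the gene end, within 1 kb of either end of a gene, which includes the 3' end. Peaks were placed by their summit at a gene end, in a gene body or between genes, and exon and intron were not told apart. For each gene, a peak overlapping the 1 kb around either end was looked for in each list. A gene called open in 1 list only lacks such a peak in the other list, which does not mean closed chromatin. Such a call can also rest on the edge of a shared peak or on a peak assigned to a neighbouring gene. Peaks were assigned to the gene with the nearest end within 100 kb, which took in 85.1% of WT and 85.6% of KO peaks. Windows of 1 Mb were ranked by their number of genes, and the GC content planned beside it was not computed. Motif shares were planned too and were not computed, since no genome sequence was used here.

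The design, the gene lists and the rule for naming genes were fixed before the data were examined. There were 20 lists of named genes, among them markers of keratinocytes, leukocytes, endothelium, Schwann cells and melanocytes, muscle, adipocytes, and bone and cartilage, and 13 families taken by gene symbol. For each list, KO-only minus WT-only peaks assigned to its members were set among 10000 random gene lists with the same number of genes per class of assigned peaks. A percentile of 97.5 or above, or 2.5 or below, was taken as standing apart. All listed symbols were found except in the interferon list, with 28 of 30, and among imprinted genes, with 30 of 36. The naming rule took Tmpo first, then per genotype the 10 genotype-only peaks of highest signal with no peak of the other list within 1 kb, at 1 peak per gene, leaving out peaks that lay in no gene and over 100 kb from any gene end. It then took the 10 genes per genotype with the largest excess of genotype-only peaks, and 3 windows per direction. From each list it took up to 4 members per direction with a gene-end peak in 1 genotype only, or 2 members with the highest shared signal where there were none. Some of the genes this rule took are not reported here.

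Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used. The code was tested on a simulated KO list made from the WT peaks. Its 88702 shared peaks were the same number that bedtools 2.31.1 found. A log2 ratio of -0.49 planted in the gene-poorest quintile of windows came back as -0.49 on average over 20 draws, and 90% of these intervals held the planted value. In the first single draw it came back as -0.52, with an interval of -0.55 to -0.49 that just missed it. With no effect planted, 92.5% of 40 intervals held 0. Of 200 random lists with nothing planted, 95.5% fell between the percentiles 2.5 and 97.5. Alternatives covered the overlap rule, the threshold, list length, the upper 50% of each list by signal, sex chromosomes, merging of close peaks, the gene-end distance, window size, and gene assignment. Further alternatives chosen after seeing the data are named as such where their values are given.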

Results

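Accessible chromatin was profiled by ATAC-seq in mouse dermal fibroblasts, the connective tissue cells of the skin. WT cells (3 libraries) were compared with cells lacking Lap2alpha (3 libraries), a nucleoplasmic splice form of lamina-associated polypeptide 2 that is encoded by Tmpo and binds A-type lamins. The series title names chromatin reorganization and a redistribution of A-type lamins after loss of the protein, and the comparison asks which accessible regions differ between the genotypes. Each genotype had 1 peak list combined over its libraries, without replicates, and the sequencing depth was unknown. Differences below therefore describe these lists and were not tested against replicate spread.

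Tmpo lies on chromosome 10 from 91147571 to 91181752. Within 10 kb of the gene, 15 WT and 13 KO peaks were called. The peak of highest signal spanned a gene end in both lists, from 91180202 to 91183042 in WT and from 91180272 to 91183014 in KO. Its summit was at 91182106 in both, at signal percentiles of 99.0 in WT and 98.8 in KO. WT-only peaks lay inside the gene at 91168147 to 91168323 and at 91179883 to 91180099, with percentiles of 13.6 and 1.97. Since Lap2alpha is 1 splice form of the gene, an open gene end in the KO list does not check the knockout.

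**Figure D1:**
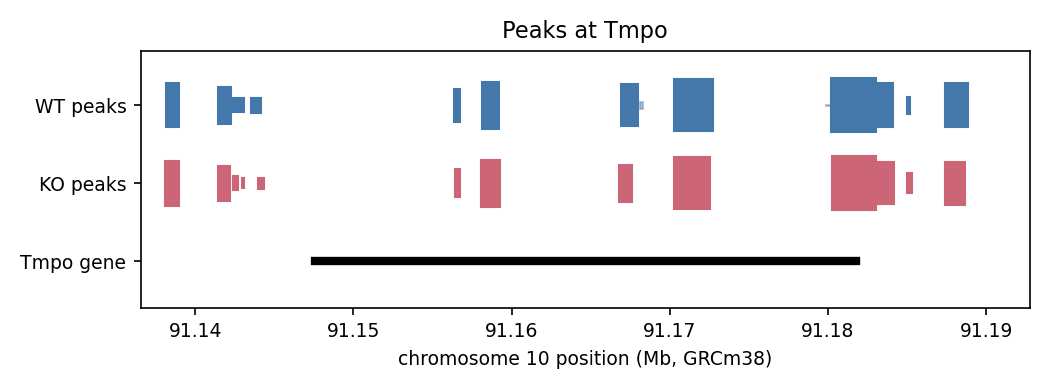
Map of peaks at Tmpo on chromosome 10 (GRCm38 position in Mb on the horizontal axis), with WT peaks above, KO peaks below them and the gene as a black bar. Box height is proportional to the signal percentile within the list, and the paler boxes are the WT-only peaks at percentiles 13.6 and 1.97.

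Most accessible regions were called in both genotypes. The WT list held 106132 peaks covering 71.0 Mb and the KO list held 98072 peaks covering 66.8 Mb, so KO had 92.4% of the WT peak number and 94.0% of its covered length. Of WT peaks, 79.6% (interval 78.5 to 80.5) overlapped a KO peak. Of KO peaks, 86.6% (interval 85.8 to 87.3) overlapped a WT peak. There were 21693 WT-only and 13162 KO-only peaks, and 16585 and 10477 of these had no peak of the other list within 1 kb. For lists of equal length, both were cut to their 73554 peaks of highest signal, 75% of the KO list. Equal length by itself brings these counts close together, and there were 11601 WT-only and 11256 KO-only peaks. With a stricter summit threshold there were 9342 and 7343. The lists had 55.5 Mb in common, which was 78.2% of the WT and 83.1% of the KO covered length.

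Genotype-only peaks were weak and narrow within their own list. Their median signal percentile was 17.8 in WT and 16.5 in KO, against 59.3 and 55.9 for shared peaks. Median widths were 231 bp for WT-only and 245 bp for KO-only peaks, against 561 bp and 545 bp for shared peaks. In the strongest decile, 11 of 10614 WT peaks and 8 of 9808 KO peaks lacked a partner, whereas in the weakest decile 37.5% of WT and 55.7% of KO peaks were shared. In the upper 50% of each list by signal, 1851 WT-only and 1181 KO-only peaks remained.

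**Figure D2:**
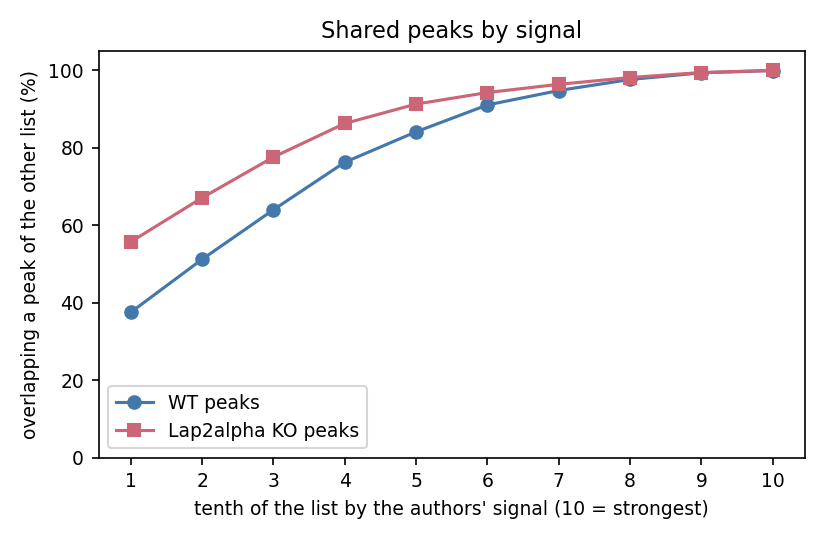
Percent of peaks overlapping a peak of the other list (vertical axis) for each decile of a list by the authors' signal (horizontal axis), for the WT and the KO list. Sharing runs from 37.5% in the weakest to 99.9% in the strongest decile of WT peaks, and from 55.7% to 99.9% of KO peaks.

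The strongest WT-only peaks lay inside genes or up to 84508 bp from the nearest gene end. The first lay inside Fhit on chromosome 14, from 9692553 to 9696531, at percentile 98.0. The next lay 44775 bp from the nearest end of Pls3, an actin-bundling protein gene on chromosome X, from 75738757 to 75741683 at percentile 97.9. At the end of Sulf1, a heparan sulfate endosulfatase gene on chromosome 1, a WT-only peak ran from 12691729 to 12694163 at percentile 94.0. Another lay at the end of Loxl4, a lysyl oxidase family gene on chromosome 19, from 42611862 to 42613688 at percentile 93.5. Others lay inside Ralyl and A830018L16Rik and nearest to Btbd35f1, Car2, Ranbp3l and Spin2g, with percentiles of 90.2 to 94.6. Of these 10 peaks, 4 were on chromosomes 4, 5, 19 and X, whose KO-to-WT peak ratio lay below that of the genome. The peaks at Fhit, Ralyl, Sulf1, Car2 and A830018L16Rik lay on chromosomes 1, 3 and 14. In their 10 Mb blocks, KO had 37.0% to 67.8% of the WT peak number.

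The strongest KO-only peaks with a gene were nearest to Sox30, inside Megf10 and inside Mbp. Of the 8 KO-only peaks in the strongest decile, 4 had no gene within 100 kb and are left out below, on chromosomes 3, 4, 6 and 19 at percentiles of 90.6 to 92.4. A further peak inside Pcm1, at percentile 90.2 and chosen after its values were seen, had a WT peak within 1 kb and was also left out by the rule. The peak near Sox30, a transcription factor gene, lay on chromosome 11 from 46025610 to 46027438, 8187 bp from a gene end, at percentile 95.5. Inside Megf10, a gene for an engulfment receptor on chromosome 18, the peak ran from 57266112 to 57267670 at percentile 93.7. Inside Mbp, the myelin basic protein gene on the same chromosome, it ran from 82546723 to 82547958 at percentile 90.7. At a gene end of Pde3a, which encodes a cyclic nucleotide phosphodiesterase, a KO-only peak on chromosome 6 ran from 141249123 to 141250674 at percentile 88.4. The others taken by the naming rule lay nearest to Cnpy1, Syn3, Dcdc5, Rin2, Csmd1 and Adm, with percentiles of 86.1 to 88.5. Of these 10 peaks with a gene, 4 were on chromosomes 6, 10, 15 and 18, whose ratio lay above that of the genome.

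WT-only peaks exceeded KO-only peaks at several genes, most of them in regions with fewer KO peaks. At 4932411N23Rik on chromosome X there were 36 WT-only peaks and 0 KO-only peaks. Synpr, a synaptic vesicle protein gene, had 17 against 0, and Pls3 had 16 against 0. Sulf1, Stxbp6, Cfap20dc and Il33, which encodes an alarmin cytokine, each had 14 against 0. Ahnak, Zmat1 and Hmga2, a gene for a chromatin architectural protein, each had 15 against 1. Sulf1, Stxbp6 and Il33 had a gene-end peak in WT only. With a stricter summit threshold Hmga2 had 2 more KO-only than WT-only peaks, which turns its direction. The excess at Ahnak and Zmat1 was then 1 peak, and that at 4932411N23Rik was 9. In the upper 50% by signal the excess was 11 at Pls3, 6 at Sulf1 and Ahnak, 5 at 4932411N23Rik, and 1 to 4 at the other genes. In the 10 Mb blocks of Ahnak and Hmga2, KO had 92.1% and 106.9% of the WT peak number. The other genes lay in blocks with 28.7% to 84.3%, so their excess cannot be told from a regional difference.

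KO-only peaks exceeded WT-only peaks at other genes. Col22a1, a collagen gene, had 20 KO-only against 6 WT-only peaks, and Tafa5 had 16 against 0. Lmcd1 and Pde3a each had 14 against 0, Ptk2b, a focal adhesion kinase family gene, had 13 against 0, and Lama4, a laminin chain gene, had 12 against 0. Hrh1, a histamine receptor gene, had 15 against 1, Atg7, an autophagy gene, had 13 against 1, and Mbnl2 had 12 against 1. Gm15319 had 20 against 3, an excess that was 0 under the stricter threshold and in the upper 50% by signal. In the upper 50% the excess was 1 at Hrh1 and Atg7, 2 at Pde3a, 8 at Lmcd1, 7 at Col22a1, 5 at Tafa5, and 4 at Ptk2b, Lama4 and Mbnl2. Lmcd1, Pde3a and Lama4 had a gene-end peak in KO only. Of these 10 genes, 7 lay on chromosomes 6, 10, 15 and 18, and of the 10 genes with a WT-only excess 5 lay on chromosomes 4, 5, 19 and X, against 26.7% of all KO-only and 25.2% of all WT-only peaks. In the 10 Mb blocks of Lama4 and Gm15319, KO had 90.8% and 98.7% of the WT peak number. The other genes with a KO-only excess lay in blocks with 107.3% to 142.3%, so their excess also cannot be told from a regional difference.

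Gene ends were mostly open in both genotypes or in neither. Of 21887 protein-coding genes, 12270 had a gene-end peak in both lists, 540 in WT only, 287 in KO only and 8790 in neither. The median signal percentile of these peaks was 91.3 at genes open in both, 29.8 at those open in WT only and 22.9 at those open in KO only. By position, 6.25% of WT-only and 4.35% of KO-only peaks had their summit at a gene end, a difference of -1.90 percentage points (interval -2.50 to -1.30). Shared WT peaks lay there in 14.8% of cases. Gene bodies held 43.6% of WT-only and 47.6% of KO-only peaks, a difference of 3.99 points (interval 1.87 to 5.92). The interval for peaks between genes, with 50.2% and 48.1%, included 0. When sharing required a reciprocal overlap of 50%, the gene-end difference was -0.10 points (interval -0.57 to 0.38).

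Collagen genes carried more KO-only than WT-only peaks. The 44 collagens had 114 KO-only and 65 WT-only peaks, at percentile 99.98 of matched random lists, whose median net was -25. By gene, 20 had more KO-only peaks, 18 had more WT-only peaks and 6 had equal numbers, so the excess came from a part of the family. Besides Col22a1, the members with the largest excess, chosen after their values were seen, were Col1a2 with 11 against 1, and Col27a1 and Col6a3 with 7 against 0 each. Col1a1, the partner chain of Col1a2 in type I collagen, had 1 KO-only and 4 WT-only peaks. Without Col22a1 the list stood at percentile 99.95.

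Mesenchymal transcription factor genes stood at percentile 99.6, with 82 KO-only and 56 WT-only peaks. Of 44 genes, 19 had more KO-only and 13 more WT-only peaks. Zeb1, a regulator of epithelial to mesenchymal transition on chromosome 18, had 10 KO-only and 0 WT-only peaks and a gene-end peak in KO only, while Ebf3 had a gene-end peak in WT only. Bone and cartilage genes stood at percentile 98.7, with 32 against 18. This rested on Sox5, a chondrocyte transcription factor gene on chromosome 6 with 11 KO-only and 0 WT-only peaks. Without Sox5 the percentile was 87.6. Matn3 and Col10a1 had a gene-end peak in WT only. In the upper 50% by signal the mesenchymal list was at percentile 88.6 and the bone and cartilage list at 91.2, inside the central range.

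The clustered protocadherins, adhesion genes in 1 cluster on chromosome 18, stood at percentile 99.2 with only 10 KO-only against 7 WT-only peaks. Of 57 members, 22 had a gene-end peak in KO only. Most Pcdhg genes share 1 annotated end, and 17 of these 22 were Pcdhg genes next to a single KO peak from 37841435 to 37841722 at signal percentile 16.7. Matched on chromosome, an alternative chosen after seeing the data, the list stood at percentile 56.8. In the upper 50% by signal it stood at 65.3, and with peaks assigned by gene body at 93.0.

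Vomeronasal receptors, olfactory receptors and ribosomal proteins carried more WT-only peaks than matched random lists. The 353 vomeronasal receptor genes had 65 WT-only and 12 KO-only peaks (percentile 0.03), and 343 had no gene-end peak in either list. The 1106 olfactory receptor genes had 89 against 25, at percentile 2.33, which was 6.13 without Olfr461 and 5.62 with peaks assigned by gene body, but 1.48 in the upper 50% by signal and 0.365 matched on chromosome. The 80 ribosomal protein genes had 78 against 13 (percentile 0.445), while 77 had a gene-end peak in both lists and none in 1 list only. In the upper 50% by signal the ribosomal protein genes stood at percentile 20.1. Of 33 lists, 4 stood above and 3 below the central 95% of random lists, where 0.825 on each side is the number that random lists give. That number holds for genes scattered over the genome, as in the random lists. It can differ for families with members that lie side by side, such as the clustered protocadherins and the vomeronasal and olfactory receptors.

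Genes of the nuclear lamina and of the Rb and E2F cell cycle pathway, to which Lap2alpha has been linked, had largely the same open gene ends. In the lamina and envelope list 27 of 30 genes had a gene-end peak in both lists and 3 in neither, the highest shared signals being at Nrm and Tmem38a, and the list stood at percentile 14.6. In the cell cycle list 39 of 40 were open in both and Ccnd3, a D-type cyclin gene, in KO only, at percentile 43.7. All 30 housekeeping genes, with Actb highest, and all 62 replication-dependent histone genes were open in both, at percentiles 23.9 and 73.5. Chromatin regulators were open in both at 37 of 40 genes, with Kdm6a and Cbx5 highest, and stress and AP-1 genes at 27 of 30, with Ier2 and Junb highest. Their percentiles were 30.8 and 93.5.

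The dermal fibroblast and matrix list held 90 KO-only and 82 WT-only peaks (percentile 93.0), with members in both directions. Its gene ends were open in both lists at 33 of 39 genes, with Thbs1 and Col5a1 highest. Senescence and secreted inflammatory factor genes had 9 KO-only and 42 WT-only peaks (percentile 3.87). Cxcl2, a neutrophil chemokine gene, was open at its end in WT only, at signal percentile 4.61. The myofibroblast list, with Srf open in WT only at signal percentile 1.59, stood at 49.6. In the Wnt list Sfrp1, Wnt10a and Wnt7b were open in WT only, at signal percentiles of 22.7, 14.2 and 3.37. Wnt4 and Rspo3 were open in KO only, at signal percentiles of 39.0 and 3.33, and the list stood at percentile 87.6. In the BMP, Hedgehog and Notch list Hhip, Ptch1 and Dll4 were open in WT only, at 49.5. Isg15 of the interferon list (16.8) and Grb10 of the imprinted list (31.3) were open in WT only.

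Markers of other cell types, apart from the bone and cartilage genes, did not stand apart. Keratinocyte genes were at percentile 31.9, with Ivl open in WT only and Itgb4 in KO only. The end peak of Itgb4 was at signal percentile 2.78, and 0 peaks assigned to Itgb4 were KO-only. Leukocyte genes were at percentile 35.7, with Itgax open in WT only and Lcp1 in KO only, at signal percentiles of 5.26 and 9.31. Endothelial genes, with Plvap and Flt1 open in both, were at 23.5. Schwann cell and melanocyte genes, with Gap43 open in WT only, were at 79.8. Skeletal muscle genes were at 20.1, with Chrna1 open in WT only and Myh3 in KO only, although 0 peaks assigned to Myh3 were KO-only. Adipocyte genes were at 86.0, with Retn open in WT only. Among families, Hox genes stood at percentile 27.2, keratins at 82.9, keratin-associated proteins at 94.95, Zfp zinc-finger genes at 67.1, solute carriers at 96.0, potassium channels at 13.4, and cadherins outside the clusters at 4.92. Solute carriers reached 98.99 in the upper 50% by signal and 97.85 with peaks assigned by gene body, and cadherins 0.49 by gene body and 2.46 matched on chromosome.

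**Figure D3:**
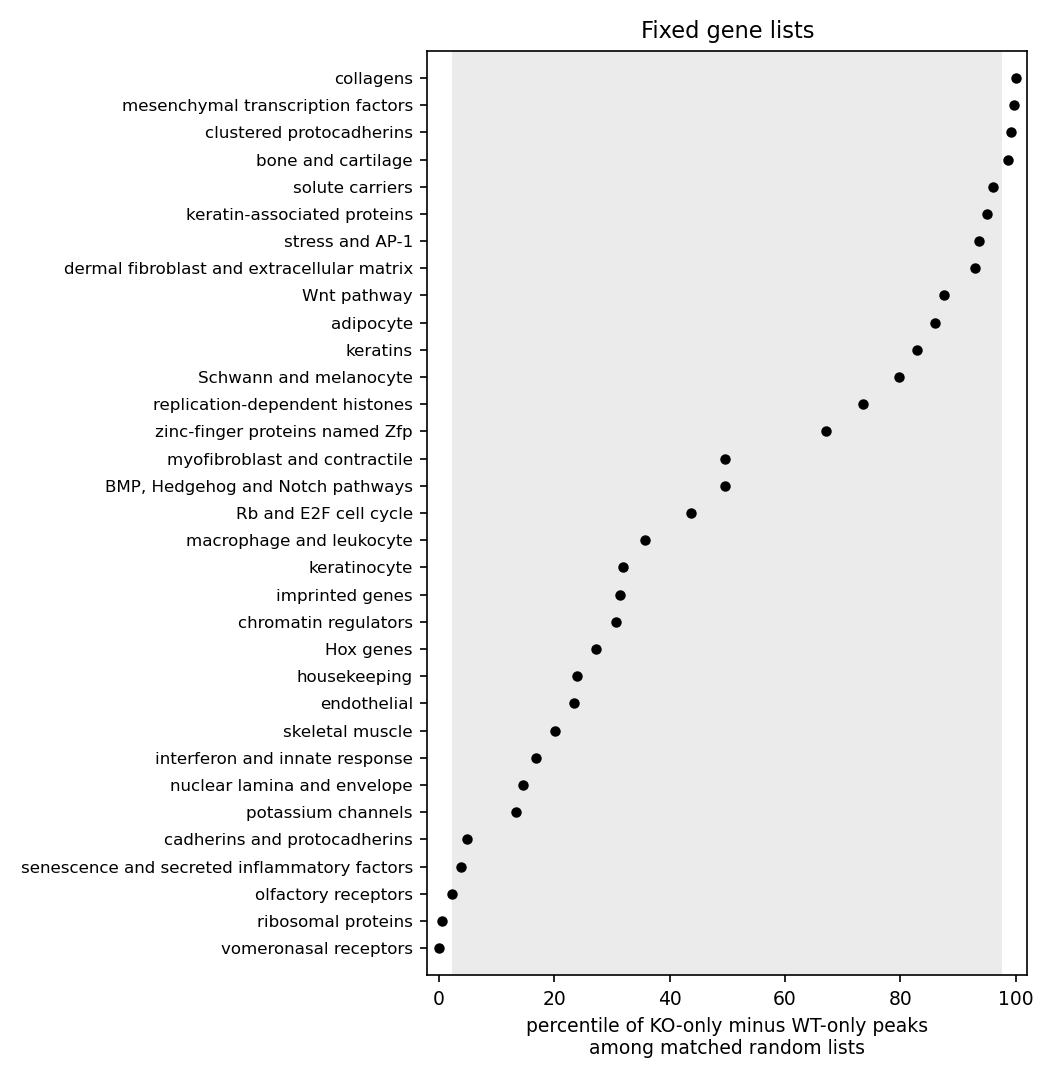
Percentile of KO-only minus WT-only peaks for each of 33 gene lists (vertical axis) among 10000 matched random lists (horizontal axis). The shaded range is the central 95%, with 4 lists above it and 3 below.

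Chromosomes differed in peak number, some along their whole length and others in part. Relative to all chromosomes, the log2 ratio of KO to WT peaks was 0.26 on chromosome 18 (interval 0.20 to 0.31), 0.18 on chromosome 6 (0.08 to 0.26), 0.11 on chromosome 15 (0.03 to 0.16) and 0.07 on chromosome 10 (0.01 to 0.12). It was -0.31 on chromosome X (-0.48 to -0.18), -0.23 on chromosome 19 (-0.32 to -0.12), -0.11 on chromosome 4 (-0.20 to -0.03) and -0.09 on chromosome 5 (-0.18 to -0.02). Chromosome Y, left out of these ratios, held 60 WT and 55 KO peaks. Each list combines 3 libraries, so these counts do not show the sex behind each library. Chromosome 18 had 751 KO-only and 328 WT-only peaks, and 9 of its 9 blocks of 10 Mb with at least 20 peaks over both lists lay above the genome ratio. Chromosome 19 had 158 against 1065 and chromosome X had 260 against 1302, with 0 of 7 and 0 of 18 blocks above it. Blocks were mixed elsewhere, with 11 of 15 above the genome ratio on chromosome 6, 9 of 11 on 15 and 9 of 13 on 10. On chromosomes 4 and 5, 3 of 16 and 4 of 16 blocks lay above it. The intervals of the other chromosomes among the 20 included 0. With the stricter summit threshold, chosen for this comparison after seeing the data, the interval for chromosome 5 also did.

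**Figure D4:**
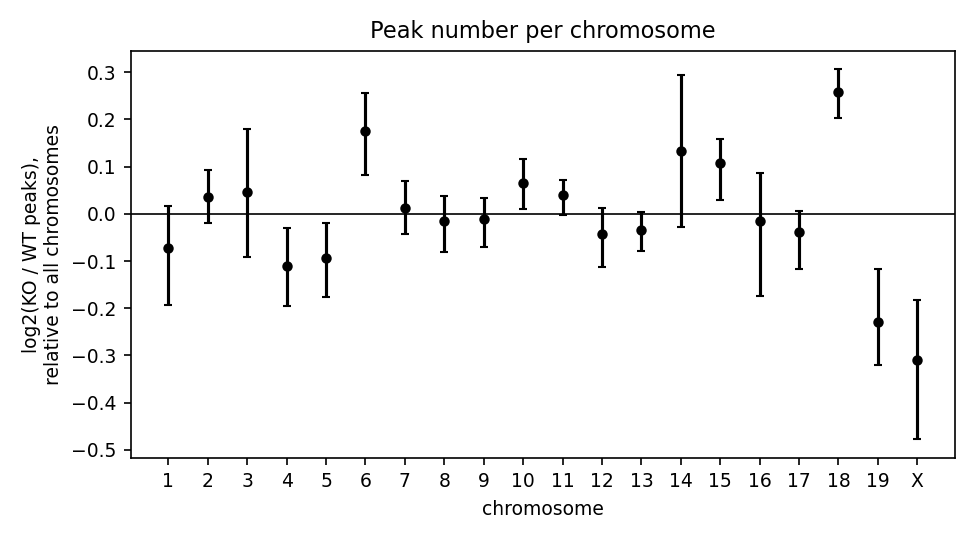
Log2 ratio of KO to WT peak number for each chromosome relative to all chromosomes (vertical axis), with 95% intervals from resampling 10 Mb blocks as bars. Chromosome 18 stands highest at 0.26 and chromosome X lowest at -0.31.

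The 3 windows of 1 Mb per direction with the largest differences lay on chromosomes X, 14, 15 and 6. On chromosome X, the window from 33000001 to 34000000 held 59 WT and 3 KO peaks and the one from 4000001 to 5000000 held 43 and 1, both among Btbd35f genes, a multi-copy family. A further window there, from 126000001 to 127000000 with 46 WT and 4 KO peaks, tied with the one from 4000001. On chromosome 14, the window from 13000001 to 14000000, with Synpr, Thoc7 and Atxn7, held 70 WT and 26 KO peaks. More KO peaks were found on chromosome 15 from 72000001 to 73000000, with Col22a1, Kcnk9 and Trappc9 (25 WT and 54 KO). The same held on chromosome 14 from 101000001 to 102000000, with Tbc1d4, Uchl3 and Lmo7 (27 and 56), and on chromosome 6 from 114000001 to 115000000, with Hrh1, Atg7 and Vgll4 (109 and 136). Of 2180 windows with at least 10 peaks, KO had under 50% of the WT number in 134, and WT had under 50% of the KO number in 22.

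Gene-poor windows held fewer KO peaks. In the quintile of 1 Mb windows with the fewest genes (median 0), there were 6366 WT and 5177 KO peaks, a log2 ratio relative to all windows of -0.18 (interval -0.27 to -0.10). In the quintile with the most genes (median 20), the ratio was 0.02 (interval 0.00 to 0.05). WT-only peaks made up 34.2% of WT peaks in the lowest and 16.8% in the highest quintile, and KO-only peaks 19.03% and 10.5% of KO peaks. In windows of 200 kb the value for the lowest quintile was -0.06 (interval -0.12 to 0.00, upper bound below 0).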

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

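Alternatives for single chromosomes, the within-chromosome and autosome-only ratios, summit-based gene ends and chromosome-matched random lists were chosen after seeing the data. Over the main results, 48 alternative values kept their call or size, 21 moved and 2 lost their call. With a reciprocal overlap of 50% there were 35631 WT-only and 27571 KO-only peaks, 66.4% and 71.9% were shared, and the gene-end difference was -0.10 points. Shared peaks came to 82.6% and 88.2% with peaks within 500 bp counted, and 82.3% and 87.7% with peaks under 1 kb apart merged. The stricter summit threshold (−log10 p at or above the WT median of 9.98) gave 9342 and 7343 peaks and 82.4% and 85.7% shared, and lists of equal length gave 11601 and 11256 peaks and 84.2% and 84.7%. The upper 50% by signal, set against the whole other list and not a filtered one, gave 1851 and 1181 peaks and 96.5% and 97.6% shared. It gave 153 and 63 genes with an end peak in WT or KO only. The overlap rules and merging move sharing by construction, and the cause of the other moves was not tested. The other alternatives for the gene-end difference lay between -3.03 and -0.93 points with intervals below 0. The gene-poor ratio lay between -0.19 and -0.06, all intervals below 0. The KO-to-WT ratio of chromosome 5, log2 relative to all chromosomes, was -0.083 with the stricter threshold (interval -0.20 to 0.01).

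The excess at Hmga2 turned to 2 more KO-only peaks with the stricter threshold, the cause was not tested. Of the other gene values 43 moved by over 1.5 times without turning direction and 73 did not. Of 99 list values 88 kept their call, 7 lost it and 4 gained one. Collagens and vomeronasal receptors kept theirs throughout. Assigned by gene body, olfactory receptors were at percentile 5.62 and clustered protocadherins at 93.0. No paired analysis was possible because each genotype's libraries were combined in 1 list. GC windows, motif shares and the promoter with an upstream and a downstream side were not run, for want of sequence and strand. Depth was unknown, so a lack of overlap between weak peaks cannot be told from sampling.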

Other observations

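Tests of the depth difference on chromosomes, of weak peaks and of gene copies in the nearly empty windows, and of whole chromosomes in gene-poor windows were chosen only after the result was seen. The genes named in the next 2 paragraphs were also chosen after their values were seen.

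Within the lists that did not stand apart, single genes leaned in opposite directions. In the dermal fibroblast and matrix list, Pdgfrb, a receptor for platelet-derived growth factor, had 9 KO-only and 0 WT-only peaks, whereas Fbn1, the fibrillin gene, had 1 against 11 and Fn1, the fibronectin gene, had 2 against 10. In the myofibroblast list, Mrtfa, a coactivator of serum response factor, had 8 KO-only and 0 WT-only peaks, Smad3 had 7 against 1, and Ankrd1 had 0 against 8. Fos and Jun, which encode AP-1 subunits, had 6 and 5 KO-only and 0 WT-only peaks each. Igfbp7, Cxcl5 and Cdkn2b of the senescence list had 0 KO-only and 6, 5 and 4 WT-only peaks. Pdgfrb, Mrtfa, Ankrd1, Igfbp7, Cxcl5 and Cdkn2b leaned in the same direction as the peak ratio of their chromosome. Their counts therefore cannot be told from a regional difference. Jun leaned against its chromosome, and Fbn1, Fn1, Smad3 and Fos lie on chromosomes whose interval included 0.

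The cadherin list was at percentile 4.92, inside the central range, but at 0.49 with peaks assigned by gene body and at 2.46 matched on chromosome, outside it. In it, 18 members had more WT-only and 4 more KO-only peaks, where the whole genome also had more WT-only peaks. Cdh11, the cadherin of mesenchymal cells, had 10 KO-only and 0 WT-only peaks. Cdh18 had 0 KO-only and 11 WT-only peaks, and Cdh1, the epithelial cadherin, 0 against 7. Chromosome 14 was split along its length: from 0 to 20 Mb, KO had 67.8% and 65.3% of the WT peak number in successive 10 Mb blocks, and from 100 to 130 Mb it had 161%, 180% and 142%. On chromosome 1 the block from 10 to 20 Mb, which holds Sulf1, had 300 WT and 111 KO peaks.

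Chromosomes with more or fewer KO peaks were weighed first. A difference of depth or threshold should leave the chromosomes alike once both lists have equal length, but the SD of the log2 ratio over all 20 chromosomes was then 0.133, against a median of 0.0557 and an upper bound of 0.0770 with 10 Mb blocks shuffled between chromosomes, which argues against it as the whole cause. A difference in DNA copy number between the cultures predicts that gene-end peaks paired 1 to 1 also rank higher in KO on chromosome 18 and lower on 19, ranks being taken within each list over the same pairs. Of gene-end pairs, 86.7% (interval 81.2 to 90.3) ranked higher in KO on chromosome 18 and 15.9% (1.02 to 27.4) on chromosome 19, against 42.1% over all chromosomes. The share was 77.2% on chromosome 6 (60.1 to 88.2), 80.5% on 15 (76.3 to 83.8), 13.4% on 4 (6.17 to 27.6) and 24.8% on X (15.9 to 31.3). The 12 chromosomes whose interval in peak number included 0 ranged from 27.0% to 63.0%, a range that holds chromosomes 5 (34.0%) and 10 (59.9%). Its upper end was chromosome 14, which had a log2 ratio in peak number of 0.13 and was split along its length. The next highest was chromosome 11 with 57.0%, below chromosome 10. The values leave copy number possible for chromosomes 18 and 15, whose intervals lie outside the range of 27.0% to 63.0%. They leave it possible with less weight for 6, 4, X and 19, whose intervals reach into that range. However, these chromosomes were picked by their peak number, and signal bears on both the rank and the calling of a peak. Such values are therefore likely under any cause of the skew and do not single out copy number. A chromosome-wide change of accessibility with genotype would give the same values and was not tested.

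Nearly empty KO windows were defined as 1 Mb windows with at least 20 WT peaks and at most 10% as many KO peaks, and there were 5, all on chromosome X, and 0 in the reverse direction. Of their 184 WT-only peaks 28.3% (interval 23.2 to 34.9 over windows) lay in the upper 50% of the WT list, against 8.36% of WT-only peaks elsewhere. The windows were chosen for few KO peaks, so 184 of their 192 WT peaks were WT-only whatever their signal. That choice alone raises the share, so the contrast cannot decide on weak peaks under the KO threshold. The 192 WT peaks had a median percentile of 36.8, and 56 of them lay in the upper 50% of the WT list. Reads shared between near-identical gene copies cannot be told apart from other causes: 20 of 24 genes there were Btbd35f or Spin2 genes, but 1 window, that of 4932411N23Rik, held none. Complete loss of this DNA from the KO culture could not be decided either, since 8 KO peaks remained and 1 of them lay in the upper 50% of the KO list. A strain difference in these copies and an effect of genotype were not tested, and either may contribute.

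Fewer KO peaks in gene-poor windows were weighed last. Were they only weaker peaks lost under the threshold, WT peaks of truly equal signal would be WT-only equally often everywhere. Within signal deciles the WT-only share was 11.1 points higher in the lowest quintile (interval 7.91 to 14.0), against 14.6 points without deciles. KO-only peaks were also more frequent there, by 3.85 points (1.84 to 5.99), so part of the difference is a lower sharing in both directions. However, the signal was measured in 1 list, and deciles are coarse: sharing of WT peaks was 37.5% in the weakest and 51.2% in the next. Peaks of the same decile can still be weaker in gene-poor windows, so these values do not decide on weak peaks. If differences between whole chromosomes were the cause, scaling each chromosome to its own ratio would remove the pattern, but the log2 ratio was then -0.19 (interval -0.27 to -0.11). This scaling leaves differences between parts of a chromosome in place, such as those on chromosome 14. These were not tested and stay open. An effect of genotype and a difference in background or depth that acts on gene-poor regions were not tested and stay open, and read counts of each library in these windows at matched depth would be needed to decide.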
